A study of Oryza sativa Indica Group with 6 samples.

How the data were processed

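Small RNA libraries were made from young panicles of greenhouse-grown rice, 2 libraries each for wild type (WT), OsRDR4 over-expression (OE) and OsRDR4 knock-down (KD). The values are read counts per distinct sequence, as deposited by the authors, who collapsed the reads of each library to distinct sequences. Trimming, the length filter and any alignment are not given in the sources used here. Each library held distinct sequences of 19 to 25 nt with whole-number counts, so the totals are those of a length class and not the full library depth, which is not given. The planned range of 18 to 30 nt could therefore not be used in full.

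Library totals ran from 6246234 to 14626742 reads. For a share of reads in 1 library the 95% Wilson interval had a half-width of between 0.011 and 0.039 percentage points for the 21-nt, 22-nt and 24-nt classes. A count of 0 allows a level of up to 3 reads, which is 0.205 to 0.480 CPM in a library and 0.119 CPM over both WT libraries. Reads without molecular identifiers are not independent molecules, so these intervals and floors cover counting error only.

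Before the data were examined, 74 mature miRNA and trans-acting siRNA sequences were listed from general knowledge of rice, with 8 lists of families by function; names follow that list and not a database release. Exact matches were counted: 61 of the listed sequences had reads and 13 had none. The monocot-restricted list shares families with the transposon-like list and miR528 with the nutrient list. No genome sequence was used, so siRNA windows and small RNAs at the OsRDR4 locus, both planned, were not counted. Fragments of 5.8S and 5S rRNA, of tRNA and of the 3' adapter were counted against sequences written down beforehand. Chloroplast 16S and psbA, the 18S rRNA 5' end, the Illumina 5' adapter and the hygromycin resistance cassette were added after the data were seen. So were the CaMV 35S promoter, the strands of an apparent artificial duplex, and animal miRNAs. Sequences of the cassette and of animal miRNAs are not printed.

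Counts were tested with edgeR's quasi-likelihood test (robust, two-sided) in 1 fit of all 6 libraries with TMM factors and library totals as above. Tested were 50 miRNAs with at least 1 CPM in at least 2 libraries and 16617 sequences with at least 5 CPM in at least 2 libraries, which held between 21.6% and 30.0% of the reads of a library. All p-values were adjusted by Benjamini and Hochberg within a comparison, and a call is an adjusted p under 0.05. The lists with at least 2 tested members were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Size classes of length and first base were tested in edgeR after the data were seen, scaled to total reads. The replicates carry numbers that do not say whether libraries of different groups belong together.

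Named miRNAs are, per comparison, up to 12 with the largest rise and 12 with the largest fall among those called with a mean of at least 5 CPM, and in any case the most abundant member of miR156, miR159, miR166, miR168, miR172, miR390, tasiR-ARF, miR396, miR444, miR528, miR820, miR2118 and miR2275. Named sequences are the 3 with the largest rise and the 3 with the largest fall, of which those matching the cassette or bacterial-like 16S rRNA are given without their sequence. Other names are given as chosen after their values were seen.

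In data simulated with the fitted dispersions, 200 of 16617 sequences were changed. The test found 59.7% of those changed 2-fold, 97.0% of those changed 4-fold and 0% of those changed 1.5-fold. It made 5 false calls (4.59% of calls). Of 12 changed miRNAs among 50, with 4 at each fold, it found 50% at 1.5-fold, 75% at 2-fold and 50% at 4-fold, with 0 false calls. The data called 12021 sequences and 33 miRNAs in OE vs WT, far more than were changed here, so these rates need not hold there. Of 7 simulated lists only the shifted one was called.

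Alternatives were the replicate number as a block, DESeq2's size factors, total reads alone, DESeq2's own test, fits of 2 groups only, other CPM minimums, added isomiRs with ends up to 2 nt away, other denominators, and leaving out each library. A fit without adapter and cassette sequences was added after the data were seen. Where leaving out a library left 1 in its group, the lone library was assumed to vary like the others. Tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.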

Results

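Small RNAs were sequenced from young rice panicles, the developing flowering branches, collected before emergence at a length of 5 to 10 cm. The plants belonged to the cultivar Pusa Basmati 1 of the Indica group. Wild-type plants (WT) were compared with plants over-expressing OsRDR4 (OE) and plants in which OsRDR4 was knocked down (KD), with 2 libraries in each of the 3 groups. OsRDR4 belongs to the RNA-dependent RNA polymerase family, enzymes that copy single-stranded RNA into the double strands from which Dicer enzymes cut small interfering RNAs. The comparisons ask which small RNAs change when OsRDR4 is raised or lowered. The level of OsRDR4 messenger RNA is not measured by libraries of this kind, so the direction of the manipulation rests on the labels.

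Each library was represented by its distinct sequences of 19 to 25 nt and their read counts. Totals in this length range were 14626742 and 10554438 reads for WT, 6954943 and 6246234 for OE, and 12228257 and 9368781 for KD. These totals cover a length class and not the whole library. The 6 libraries together held 18396517 distinct sequences, and between 77.4% and 79.9% of the distinct sequences in a library were read once. Levels are given as CPM, the usual scaling of read counts to the library total, as mean ± SD of 2 libraries. Replicates of a group differed by more than sampling noise, with chi-square values per degree of freedom of 1.79 for WT, 2.05 for OE and 1.62 for KD. The labels do not say that replicates came from separate plants or harvests. The p-values therefore measure the spread between these libraries, which may be technical. The edgeR test also shares its estimate of spread across all tested miRNAs or sequences. Very small p-values therefore do not rest on the 2 libraries of a group alone.

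The 21-nt class held a smaller share of reads in OE than in WT. Reads of 21 nt made up 18.8% ± 2.65 of the WT libraries (SD, n = 2), 10.4% ± 0.737 of OE and 19.6% ± 1.71 of KD. The 24-nt class, which in plants is dominated by siRNAs of the RNA-directed DNA methylation pathway, was the most abundant class in every library, with 54.8% ± 3.0 in WT, 58.2% ± 2.16 in OE and 52.9% ± 1.44 in KD. Reads of 22 nt made up 4.42% ± 0.234 in WT, 5.85% ± 0.514 in OE and 4.92% ± 0.0580 in KD. For the 21-nt and 22-nt shares both OE libraries lay outside the range of the WT libraries, which chance gives with a probability of 0.33 at 2 against 2, while the 24-nt shares of OE and WT overlapped. Counted over distinct sequences, the 21-nt shares of WT (7.68% ± 0.827) and OE (7.16% ± 0.529) overlapped, and the 24-nt share of OE minus that of WT was -0.98 percentage points. The 21-nt share of KD minus that of WT was 2.61 percentage points without WT replicate 1 and -1.14 without WT replicate 2. An exact two-sided permutation test of 2 against 2 libraries cannot give a p below 0.33, so these shares are described only.

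**Figure D1:**
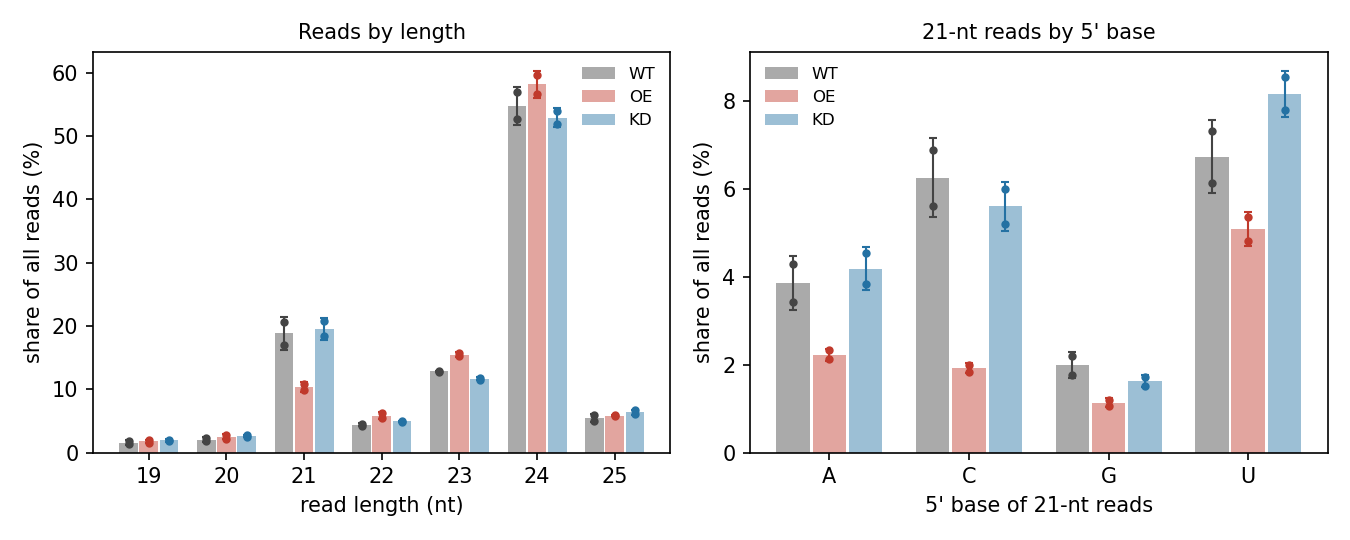
Share of all reads (y axis, percent) by read length (x axis, left) and, for 21-nt reads, by 5' base (x axis, right) in WT, OE and KD libraries; bars are means, error bars are SD of 2 libraries and points are libraries. The 21-nt class is 10.4% in OE against 18.8% in WT, and the loss is steepest for 21-nt reads that begin with C, at 1.91% in OE against 6.25% in WT.

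The loss of 21-nt reads in OE fell mainly on those beginning with cytosine. Such reads took 6.25% ± 0.904 of the WT libraries, 1.91% ± 0.112 of OE and 5.60% ± 0.554 of KD (SD, n = 2), an OE to WT ratio of 0.306. The ratio was 0.576 for a 5' A, 0.569 for a 5' G and 0.756 for a 5' U. Within the 21-nt class the share of 5' C was 33.2% in WT, 18.5% in OE and 28.6% in KD. In a test of 28 classes of length and first base, added after the values were seen, the 21-nt 5' C class fell by 1.71 on the log2 scale in OE (SE 0.133, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000534). The same class had a log2 fold change of -0.16 in KD (SE 0.130, adjusted p = 0.416, edgeR).

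The first question was which microRNAs (miRNAs) differ when OsRDR4 is over-expressed. In OE, miRNAs that trigger phased siRNAs of the reproductive tissue fell, while miRNAs tied to phosphate and copper supply rose. Both lists moved in the same direction in KD, so neither change can be assigned to a raised level of OsRDR4. Of 50 listed miRNAs with enough reads, 33 differed from WT, 15 higher and 18 lower (edgeR quasi-likelihood test, two-sided, adjusted p under 0.05). With DESeq2's size factors in edgeR, which shift the fold changes by 0.28 against scaling to total reads where TMM shifts them by -0.0054, the split was 18 higher and 13 lower. DESeq2's own test gave 15 higher and 8 lower.

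The reproductive phasiRNA triggers are miR2118, which starts the 21-nt phased siRNAs of young anthers, and miR2275, which starts the 24-nt ones at meiosis. All 5 measured members fell in OE. The miR2118 family together stood at 87.0 ± 11.1 CPM in WT and 13.7 ± 1.68 in OE (SD, n = 2). miR2118f changed from 19.7 ± 4.26 to 1.02 ± 0.827 CPM, a log2 fold change of -4.30 (SE 0.305, edgeR adjusted p = 7.35e-28). With the replicate number as a block the edgeR adjusted p of miR2118f was 1.06e-10. Its log2 fold change was -3.66 without OE replicate 1 and -5.42 without OE replicate 2. miR2118d changed by -2.94 on the log2 scale and miR2118b by -1.78. miR2275a had a log2 fold change of -2.04 at 1.30 ± 0.0959 CPM in WT (edgeR adjusted p = 0.00371), and lost its call with DESeq2 (adjusted p = 0.192) and without WT replicate 2 (0.0639). The list as a whole was lower than the other miRNAs (camera adjusted p = 0.00640), with an adjusted p = 0.183 with an estimated correlation. The count adjusted over the list alone was also 5.

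Fragments matching chloroplast RNA, taken here as a mark of green tissue, were higher in OE and KD, where the trigger miRNAs were lower. Whether they reflect green tissue or breakdown of chloroplast RNA was not tested. Sense fragments of the chloroplast 16S rRNA stood at 41.8 ± 0.00747 CPM in WT, 631 ± 77.5 in OE and 243 ± 3.05 in KD (SD, n = 2), and fragments of the photosystem gene psbA at 4.81 ± 0.0328, 35.5 ± 5.48 and 16.8 ± 1.97 CPM. The chloroplast tRNA-His 5' end, the chloroplast reference fixed beforehand, was highest in KD. It stood at 0.347 ± 0.0891 CPM in WT, 0.760 ± 0.0577 in OE and 1.25 ± 0.496 in KD, from few reads.

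**Figure D2:**
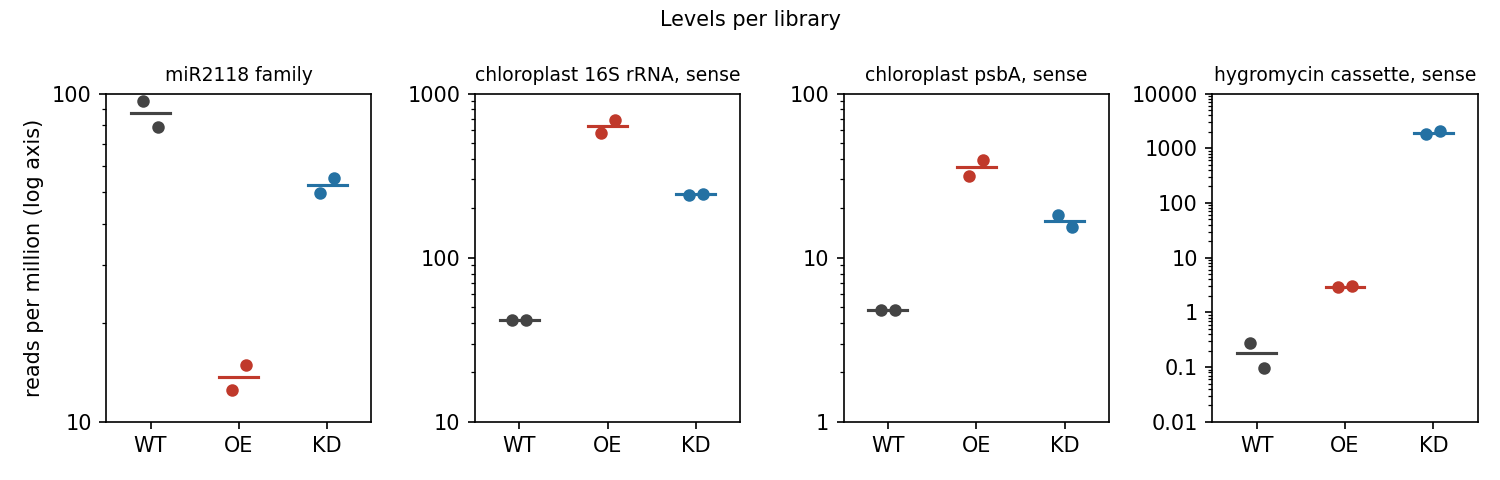
CPM (y axes, log scale, each panel with its own range) of the miR2118 family, sense chloroplast 16S rRNA fragments, sense psbA fragments and sense reads of a hygromycin resistance cassette in WT, OE and KD (x axis); points are libraries and lines are means of 2 libraries. The miR2118 family is lowest in OE (13.7 CPM) and the chloroplast fragments are highest there (631 and 35.5 CPM), while the cassette reads stand at 1935 CPM in KD.

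The nutrient and copper list rose in OE with 6 of 6 measured members higher (camera adjusted p = 0.00777, adjusted p = 0.183 with an estimated correlation, 6 adjusted over the list alone). miR399d, a miRNA of phosphate starvation, had 0.184 ± 0.126 CPM in WT and 3.89 ± 0.831 in OE, a log2 fold change of 4.25 (SE 0.503, edgeR adjusted p = 1.29e-13) that was 5.03 without WT replicate 1. miR827, which acts on phosphate transporters, rose by 1.55 on the log2 scale. The copper miRNAs miR408, miR398b and miR528 rose by 2.36, 1.34 and 0.79.

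Among the miRNAs of floral and meristem development 6 rose and 9 fell of 22, and the list showed no common direction (camera adjusted p = 0.941; median log2 fold change -0.40, mean 0.043, test direction up). miR396e, a regulator of growth-regulating factors, rose from 2241 ± 437 to 8191 ± 405 CPM, a log2 fold change of 1.88 (SE 0.107, edgeR adjusted p = 1.15e-36), while miR396c fell by 1.55. Reads were assigned by exact sequence, which does not separate loci that share a mature sequence. miR167d rose by 1.70, miR164a by 0.59 and miR159a by 0.53. miR166a, which targets class III homeodomain leucine zipper genes, was the most abundant miRNA in WT and KD, second to miR396e in OE, and changed from 11033 ± 1345 to 7366 ± 704 CPM, a log2 fold change of -0.59 (SE 0.0939, edgeR adjusted p = 1.61e-08). miR166k fell by 1.39, miR166g by 0.61, miR166m by 0.51 and miR171b by 0.73. miR172a, which acts on APETALA2-like genes, had a log2 fold change of -1.62 at 2.16 ± 0.158 CPM in WT (edgeR adjusted p = 0.00346).

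By camera the other lists gave no call in OE. By fry, which asks whether a list moves on balance and does not compare it with other miRNAs, the SPL-targeting list rose (adjusted p = 0.0241, and 0.148 with total reads). Fry's mixed form, for change in either direction, called 6 of the 7 lists, with the silencing feedback list as the exception. Among the SPL-targeting miRNAs miR156a rose by 1.48 on the log2 scale, the only called member (camera adjusted p = 0.692). The list does not hold a more abundant 21-nt sequence with 1 mismatch from the listed miR529b. That sequence stood at 5364 ± 1080 CPM in WT and 5521 ± 182 in OE (SD, n = 2). miR390, the trigger of trans-acting siRNAs, was the only measured member of its list and fell by 0.76, and the 2 listed tasiR-ARF sequences had 0 reads in all 6 libraries. Neither of the 2 silencing feedback miRNAs passed the test (camera adjusted p = 0.941), with a log2 fold change of -0.00054 for miR168a, the regulator of AGO1, which was 0.29 with DESeq2's size factors. Of 10 monocot-restricted miRNAs 2 rose and 3 fell, with miR444b at -0.63. Their median log2 fold change was -0.18, their mean 0.35, and the direction of the test was down (camera adjusted p = 0.941). The mean is above 0 through miR1432, fitted at 6.34 over 0 reads in WT, a value with no finite estimate. Of 5 transposon-like and 24-nt miRNAs 2 fell (camera adjusted p = 0.683), with miR1862a at -1.50, and miR820a had a log2 fold change of 0.44 (edgeR adjusted p = 0.295). The counts adjusted over the list alone equalled those over all 50 miRNAs in these lists and in those of the other comparisons.

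Some of these calls rested on single libraries. Without WT replicate 2 the calls of miR159a (edgeR adjusted p = 0.0986) and miR172a (0.153) were lost, and without OE replicate 1 those of miR172a (0.0937), miR444b (0.0560) and miR528 (0.0719). The call of miR166m was lost without any of the 4 libraries, at adjusted p between 0.0615 and 0.267. Without OE replicate 2 miR172a was at -2.22.

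Other calls in OE rested on the test or the scaling. With DESeq2 those of miR390 (log2 fold change -0.47, adjusted p = 0.161), miR171b (-0.44, 0.226), miR444b (-0.33, 0.192), miR172a (-1.40, 0.192) and miR166m (-0.23, 0.637) were lost. With DESeq2's size factors in edgeR miR172a (0.0520), miR444b (0.0924) and miR166m (0.358) no longer passed, and with total reads miR166m did not (0.124).

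At the level of single sequences the OE profile stood far from WT. Of 16617 sequences with at least 5 CPM in at least 2 libraries, 12021 differed, 5892 higher and 6129 lower (edgeR, adjusted p under 0.05). Among 21-nt sequences 237 of 3606 were higher and 3020 lower, with a median log2 fold change of -2.28, and among those with a 5' C 53 of 1332 were higher and 1208 lower. Among 24-nt sequences 4377 of 10245 were higher and 2636 lower, and a 5' C was found in 1239 of the higher and 465 of the lower ones. A few abundant sequences, chosen after their values were seen, show the size of these changes. The 24-nt TTCGGCTTTGGACCAGCTTGGCCT stood at 3585 ± 209 CPM in WT and 138 ± 7.55 in OE, the 21-nt CCTTCTGTACTGAACATGCCT at 2837 ± 542 and 188 ± 10.6, and the 21-nt CAAGACTCTCTTGAAACGCCT at 1443 ± 146 and 119 ± 8.61 (SD, n = 2).

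Some sequences were read in one group and not in the other. The 22-nt AGAAATACCCAATATCTTGCTG had 0 reads in WT, 53.4 ± 7.06 CPM in OE and 11.7 ± 0.558 in KD (SD, n = 2). Against a floor of 3 reads over both WT libraries (0.119 CPM) it was at least 449-fold higher in OE. The 24-nt AGGCGACGAGATCATGTTAGGATG stood at 19.1 ± 0.809 CPM in OE, at least 160-fold above the same floor. The third largest rise was a 21-nt sequence from a conserved region of 16S rRNA, which is not printed because the reference used does not settle whether it is plastid or bacterial. It had 0 reads in WT, 18.1 ± 1.31 CPM in OE, at least 152-fold above the floor, and 5.18 ± 0.971 CPM in KD. The 24-nt AATCAGGACCCACTATATCAGGAG had 33.1 ± 4.98 CPM in WT and 57.4 ± 2.62 in KD but 0 reads in OE, which is at least 145-fold lower. GATGTTAGAACTTAGAAAAGGCCT, also of 24 nt, had 28.8 ± 4.96 CPM in WT and 0 reads in OE and in KD. GCGGGTCTGCAAGTTAACAAGCCT had 22.5 ± 1.90 CPM in WT and 0 reads in OE. These floors cover counting error only.

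The second question was which miRNAs differ when OsRDR4 is knocked down. Of the phosphate and copper miRNAs, miR827 and miR398b rose more strongly in KD than in OE and miR408 less strongly, and the list was not called between OE and KD by camera (adjusted p = 0.951). The miR2118 members fell, with miR2118f and miR2118d falling less than in OE. Of the 50 miRNAs 25 differed from WT, 11 higher and 14 lower (edgeR, adjusted p under 0.05). The direction of the smaller changes depends on the scaling: TMM moved the KD to WT fold changes by -0.62 on the log2 scale against scaling to total reads, and total reads gave 26 higher and 3 lower. DESeq2's own test gave 10 higher and 8 lower. Reads of all listed miRNAs made up 1.70% ± 0.238 of WT, 1.83% ± 0.0438 of OE and 2.53% ± 0.195 of KD (SD, n = 2). Over the tested sequences TMM moved the KD to WT fold changes by only -0.060 against total reads. The miRNA and sequence fold changes of KD therefore rest on different scalings.

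In the nutrient and copper list 5 of 6 members rose in KD (camera adjusted p = 0.00131, adjusted p = 0.155 with an estimated correlation, 5 adjusted over the list alone). miR399d reached 11.3 ± 2.52 CPM, a log2 fold change of 5.17 (SE 0.401, edgeR adjusted p = 1.99e-24), and miR827 reached 20.4 ± 5.07 CPM from 1.63 ± 0.0213 in WT, a log2 fold change of 3.04. Without WT replicate 1 the value of miR399d was 5.95. miR398b rose by 2.37, miR408 by 0.93 and miR528 by 0.82. miR397a, named after its values were seen, was at 1.65 in OE and -0.36 in KD. All 5 phasiRNA triggers fell (camera adjusted p = 0.00196, adjusted p = 0.155 with an estimated correlation, 5 adjusted over the list alone). The miR2118 family stood at 52.6 ± 3.96 CPM. The log2 fold changes were -1.82 for miR2118f, -1.36 for miR2118b, -1.15 for miR2118d and -1.23 for miR2275a. They remained below 0 with total reads, at -1.22, -0.74, -0.54 and -0.65, where 3 of the 5 were called and miR2118a and miR2275a (edgeR adjusted p = 0.278) were not. The call of miR2275a was also lost without WT replicate 1 (0.0613), WT replicate 2 (0.0727) or KD replicate 2 (0.123), and its value was -1.87 without KD replicate 1. A fit of only WT and KD did not call it either (0.0723). Chloroplast 16S fragments in KD were 5.82-fold above WT.

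Of the 22 developmental miRNAs 4 rose and 5 fell in KD. Their median log2 fold change was -0.039, their mean 0.11, and the direction of the test was down (camera adjusted p = 0.860). miR167d rose by 1.27, miR396e by 0.63, miR164a by 0.60 and miR160a by 0.57. miR172a fell by 1.27 and miR171b by 0.75, but with total reads they were at -0.69 (edgeR adjusted p = 0.146) and -0.15 (0.654) and were not called. miR396a, miR166k and miR396c had log2 fold changes of -0.59, -0.55 and -0.51, and miR1862a had -0.48; all 4 were above 0 when scaled to total reads (0.018, 0.066, 0.105 and 0.156). miR166a was at -0.18, miR390 at -0.20 and miR444b at -0.14 without passing the test. These also changed sign with total reads, where miR166a passed as higher (0.43, edgeR adjusted p = 0.0393). With the replicate number as a block miR166a passed as lower (0.0171) and miR1862a lost its call (0.0653). miR156a, miR159a, miR168a and miR820a stood at 0.29, 0.30, 0.28 and 0.25 without passing, and these 4 also passed as higher with total reads, at 0.89, 0.91, 0.89 and 0.84 (edgeR adjusted p = 0.00794, 0.000686, 0.000686 and 0.0317).

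miR162a, which targets DICER-LIKE1, rose by 0.43, and so 1 of the 2 silencing feedback miRNAs was called (camera adjusted p = 0.860). Of the 10 monocot-restricted miRNAs 2 rose and 4 fell, including miR1425 at -0.75, which was -0.14 and not called with total reads (edgeR adjusted p = 0.633). Their median log2 fold change was -0.31, their mean 0.66, and the direction of the test was down (camera adjusted p = 0.860). The mean is above 0 through miR1432, fitted at 9.22 over 0 reads in WT, a value with no finite estimate. Of the 5 transposon-like and 24-nt miRNAs 2 fell (camera adjusted p = 0.819), and of the 4 SPL-targeting miRNAs 0 passed in edgeR (camera adjusted p = 0.860). The SPL-targeting result does not cover the unlisted 21-nt sequence with 1 mismatch from miR529b. That sequence stood at 5364 ± 1080 CPM in WT and 11746 ± 2241 in KD (SD, n = 2). The listed miR529b stood at 1.20 ± 0.230 CPM in WT and 2.56 ± 0.610 in KD. With total reads the calls in KD were 13 higher and 0 lower for the developmental list, 4 and 0 for the monocot-restricted list, and 2 and 0 each for the transposon-like, SPL-targeting and feedback lists. By fry 2 lists were called in KD, the triggers and the nutrient and copper list, and 7 with total reads. miR1432, named after its values were seen, had 0 reads in both WT libraries, 3 and 8 in OE, and 101 and 103 in KD.

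WT replicate 2 carried several of the KD calls. Without it miR396e (edgeR adjusted p = 0.0571), miR164a (0.0611), miR162a (0.0852), miR528 (0.0990), miR172a (0.124), miR1862a (0.124) and miR160a (0.155) no longer passed, while miR444b (0.0116), miR166a (0.0198) and miR390 (0.0235) passed as lower. Without WT replicate 1 miR408 (0.0791) and miR162a (0.222) were lost, and without KD replicate 2 miR160a (0.0744), miR1862a (0.121) and miR172a (0.139). Without KD replicate 1 miR159a (6.94e-10) and miR168a (3.08e-07) passed as higher, and miR172a was at -2.33. With DESeq2 miR160a (0.0912), miR1862a (0.111) and miR172a (0.212) were not called. A fit of only WT and KD called 19 miRNAs and lost miR160a (0.0678), miR162a (0.0833), miR172a (0.102) and miR1862a (0.147).

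**Figure D3:**
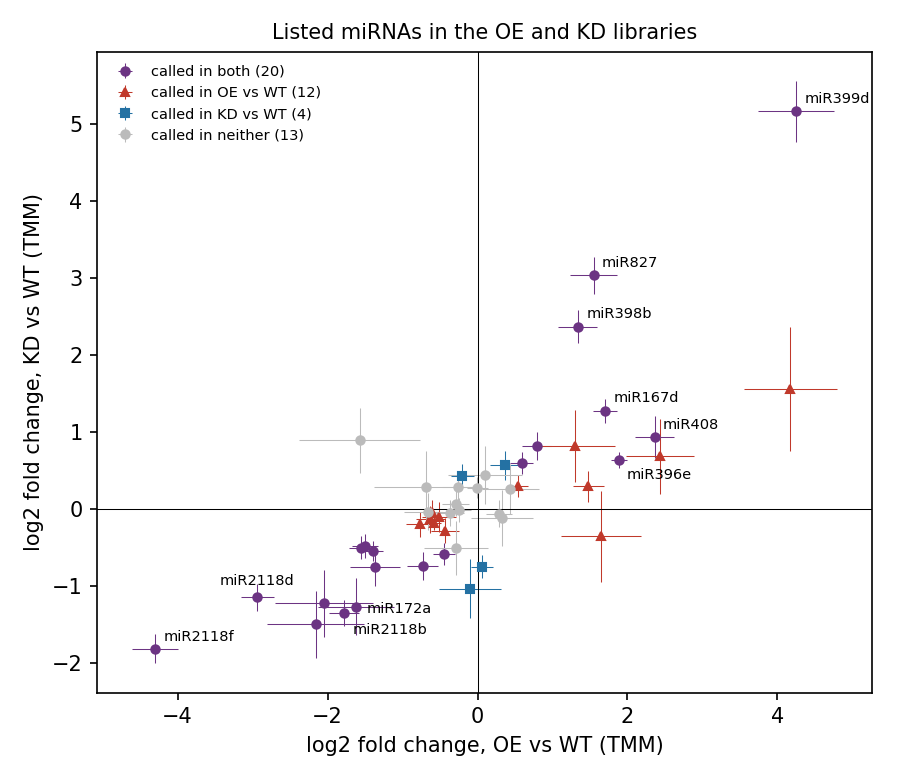
Log2 fold change of 49 listed miRNAs in KD vs WT (y axis) against OE vs WT (x axis), TMM scaling, with bars of 1 SE; symbols mark which comparison called the miRNA, and miR1432, with 0 reads in WT, is not drawn. miR399d, miR827 and miR398b lie high in both comparisons and the miR2118 members low in both; scaling to total reads would raise the KD values by about 0.62.

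Fewer single sequences differed in KD than in OE. Of the 16617 sequences 7257 differed from WT, 3567 higher and 3690 lower (edgeR, adjusted p under 0.05), and DESeq2 called 4778. Without KD replicate 1 the edgeR count was 4846. Among 21-nt sequences 481 were higher and 1232 lower, and among 24-nt sequences 2329 were higher and 1896 lower. Of the 481 higher 21-nt sequences 76 matched a hygromycin resistance cassette, the selection marker of many plant transformation vectors. The 3 largest increases in KD were of this kind. Cassette sequences could pass the filter only through the KD libraries. The largest decreases were AAGGCACTGAATCTGGTTAACGGA, with 46.4 ± 4.04 CPM in WT and 0 reads in KD, TCTGATATAAGGGCATACGAGGA, with 41.2 ± 1.39 CPM in WT and 0 reads in KD, and GATGTTAGAACTTAGAAAAGGCCT. Against a floor of 3 reads over both KD libraries these were at least 334-fold, 296-fold and 207-fold lower.

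OE and KD were also compared directly. The phasiRNA triggers miR2118f and miR2118d were lower in OE than in KD, by -2.47 and -1.78 on the log2 scale, and 2 of the 5 triggers were called. The value of miR2118f was -1.84 without OE replicate 1 and -3.59 without OE replicate 2. miR408, miR396e, miR156a, miR1425 and miR167d were higher in OE, by 1.43, 1.25, 1.19, 0.81 and 0.43; with total reads miR167d reversed, at -0.19, and miR156a (0.56, edgeR adjusted p = 0.0640) and miR1425 (0.20, 0.425) lost their calls. miR827, miR398b and miR399d were lower in OE, by -1.49, -1.03 and -0.92. Also lower were miR396c (-1.04), miR1862a (-1.02), miR166k (-0.84), miR162a (-0.63), miR166g (-0.57), miR390 (-0.56), miR167a (-0.54), miR444b (-0.49) and miR166a (-0.40). With DESeq2's size factors 6 of these were not called, miR162a (-0.37, edgeR adjusted p = 0.0554), miR166g (-0.31, 0.0552), miR390 (-0.30, 0.147), miR167a (-0.28, 0.241), miR444b (-0.23, 0.307) and miR166a (-0.14, 0.329). DESeq2's own test did not call them either, nor miR399d (adjusted p = 0.296). A fit of only OE and KD called 19 miRNAs, 10 higher and 9 lower in OE, and lost these same 7 at adjusted p between 0.0672 and 0.156. miR159a, miR820a, miR528, miR168a, miR172a and miR2275a were at 0.24, 0.18, -0.028, -0.28, -0.35 and -0.82 without passing the test; with total reads miR168a (-0.90, edgeR adjusted p = 0.000459) and miR528 (-0.65, 0.00920) passed as lower, and with DESeq2's size factors miR159a (0.51, 0.00454) passed as higher.

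Among these calls, miR166g (edgeR adjusted p = 0.0624), miR399d (0.0992), miR167d (0.139), miR167a (0.168), miR444b (0.182) and miR390 (0.219) were lost without OE replicate 1. Without OE replicate 2 miR167d (0.0536), miR167a (0.0995) and miR444b (0.115) were lost, without KD replicate 1 miR444b (0.0643) and miR167d (0.0943), and without KD replicate 2 miR390 (0.0882), miR444b (0.123) and miR167a (0.254). miR168a passed without KD replicate 1 (3.25e-07), and miR159a without KD replicate 2 (2.40e-09).

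Of the 50 miRNAs 24 differed between OE and KD, 8 higher and 16 lower in OE (edgeR, adjusted p under 0.05). The split was 5 and 29 with total reads, 12 and 10 with DESeq2's size factors and 10 and 8 with DESeq2. No list was called: the camera adjusted p was 0.651 for the phasiRNA triggers, 0.951 for the nutrient and copper list and for the monocot-restricted list, 0.913 for the transposon-like list and 0.764 for the other 3; camera gave 0 lists at an unadjusted p under 0.05. By fry the triggers were lower on balance (adjusted p = 0.00870), and 6 lists were called with total reads. At the level of sequences 12466 of 16617 differed, 5965 higher and 6501 lower in OE, and 3053 of 3606 sequences of 21 nt were lower. AAGGCACTGAATCTGGTTAACGGA, ACCGACAGACTGGAGAGCATCAGC and AGGATCACCCTCTATCTTGGCTCC were the largest increases, with 60.9 ± 19.8, 58.8 ± 5.64 and 32.1 ± 4.58 CPM in OE and 0 reads in KD, and the 3 largest decreases matched the hygromycin cassette.

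Calls in the same direction were common among the miRNAs that changed against WT. With TMM scaling 9 miRNAs were higher and 12 lower in both comparisons, and 0 were called in opposite directions. By the labels OsRDR4 was manipulated in opposite directions in OE and KD. Effects of transformation that both groups may share were not tested. With total reads only 3 miRNAs were lower in KD, so no more than 3 could be lower in both, and miR166a was called in opposite directions, lower in OE and higher in KD. Independent lists of these sizes would share 3.30 and 5.04. Both comparisons use the same WT libraries, and 20 simulated data sets with no change gave means of 0 and 0.05 shared calls. A test at adjusted p under 0.05 makes few calls where nothing changes. These counts therefore cannot show how many of the shared calls come from the shared controls. The fold changes of the 50 miRNAs had a covariance of 2.61 against 0.0863 in the simulation. Their correlation across miRNAs, which are not independent replicates, was 0.824 against 0.451. The 50 include miR1432, with 0 reads in WT and fitted log2 fold changes of 6.34 in OE and 9.22 in KD. Such values have no finite estimate and weigh on both measures. For the 16617 sequences 1659 were higher and 2316 lower in both and 1285 moved in opposite directions, against 1265 and 1361 expected of independent lists, with a covariance of 1.01 against 0.0522. Their correlation across sequences was 0.275, below the 0.421 of the simulation. The 2 WT libraries could not be split between the comparisons, so part of the excess may come from the shared controls. Across the tested sequences the rank correlation of levels was 0.956 between WT replicates, 0.946 between OE replicates and 0.956 between KD replicates, between 0.625 and 0.652 for WT against KD libraries, and between 0.151 and 0.208 for WT against OE libraries.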

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

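The 5 tests of explanations in this part were chosen after the results were seen. The signals listed first come from references outside the miRNA lists and stood above the WT libraries. Sequences of the cassette are also among the sequences tested in the report, 96 of them, all higher in KD. With 9 cassette reads in WT and 57 in OE, they could pass the filter only through the KD libraries. Their calls were therefore fixed by the filter. Reads of a hygromycin resistance cassette stood at 3266 ± 229 CPM in KD and 4.30 ± 0.423 in OE, against 0.334 ± 0.204 in WT (SD, n = 2). Reads of any length within 1 strand of an apparent artificial small RNA duplex, all its end variants together, stood at 163 ± 12.5 CPM in KD, with 2 reads in WT and 1 in OE; the most read of these variants alone stood at 126 ± 8.82 CPM. Sequences of 4 animal miRNAs together stood at 40.0 ± 5.54 CPM in KD, with 8 reads in WT and 0 in OE. Chloroplast 16S rRNA fragments stood at 631 ± 77.5 CPM in OE and 243 ± 3.05 in KD, against 41.8 ± 0.00747 in WT. Fragments of psbA stood at 35.5 ± 5.48 CPM in OE and 16.8 ± 1.97 in KD, against 4.81 ± 0.0328 in WT.

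The miR2118 family and the 21-nt reads with a 5' C were low in OE, and miR2118 was lower in KD too. In KD miR2118f, miR2118b and miR2118d were at -1.82, -1.36 and -1.15 on the log2 scale. With total reads, which remove a TMM shift of -0.62, they were at -1.22, -0.74 and -0.54. In OE none of the scalings used accounts for the fall. With TMM, DESeq2's size factors and total reads, or in DESeq2's own test, the weakest miR2118 log2 fold change of OE was -1.49. Against total reads, TMM shifted OE vs WT by only -0.0054 and DESeq2's size factors by 0.28. These scalings could not bring such changes near 0, so a larger error of scaling was not tested. A difference in stage or tissue makeup of the panicles may contribute, as chloroplast 16S fragments were 15.1-fold above WT in OE and 5.82-fold in KD, the order of the miR2118 loss. An effect of OsRDR4 itself in 1 or both groups, and effects of transformation, stay open as untested.

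Some 24-nt sequences had at least 1.5 CPM in both libraries of one group and 0 reads in both of another. There were 330 present in WT and unread in OE, 516 in WT and unread in KD, 93 in OE and 147 in KD unread in WT, 526 in OE unread in KD, and 350 in KD unread in OE. Lower depth as the whole cause is argued against. At their level in the group that held them, each of these sequences would give at least 19.9 reads in the group without it. This minimum follows from the cut-off of 1.5 CPM and the depth of the groups. Of the sequences of WT, 1.56 times as many were unread in KD as in OE, although KD had 21597038 reads and OE 13201177. The 95% Wilson interval of 1.36 to 1.80 treats sequences as independent, but some were unread in both groups. Single-base strain variants at positions 5 to 20 are argued against as well, for partners with at least 0.5 CPM in both libraries of the other group. A substitution partner was found for 0 of 1962 pairs of a sequence and a group without it. This would allow up to 0.153% if the pairs were independent, but some sequences count in more than 1 pair. The search found 350 of 350 planted partners, which shows only that the lookup works, since each was placed in the searched set. Larger sequence differences between the plants and a gain or loss of siRNAs at whole loci with OsRDR4 could each give this pattern and were not tested.

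The cassette reads of KD were 41487 sense and 28588 antisense, and 80.0% of them were 21 nt long. Fragments of degraded cassette mRNA are argued against by the antisense share of 40.8%. The reads are consistent with siRNAs cut from double-stranded RNA of a silenced transgene, a hypothesis found from these same reads. The labels do not give the constructs, so whether OE plants carry the same cassette, at 57 reads in OE against 9 in WT, stays open. A link to the level of OsRDR4 was not tested.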

How the results depend on the processing

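All alternatives here were planned except the fit without adapter and cassette sequences, which was chosen after the data were seen. With the replicate block the calls were 33, 25 and 25 miRNAs for OE vs WT, KD vs WT and OE vs KD, 11671, 6584 and 12188 sequences, and by camera 2, 2 and 0 lists. Of the named miRNAs the block ended the KD vs WT call of miR1862a (adjusted p = 0.0653) and gave miR166a one (0.0171). Fits of 2 groups only called 34, 19 and 19 miRNAs and 11662, 7555 and 12492 sequences. Deviations of same-numbered replicates correlated between -0.29 and 0.12, so the numbers do not show a pairing. By camera the lists were also 2, 2 and 0 with total reads. With an estimated correlation camera called 0 lists in these fits and in that of the report (lowest adjusted p 0.155). Fry called 3, 2 and 1 lists in the fit of the report, 3, 2 and 2 with the block, and 3, 7 and 6 with total reads. The 3 lists of OE vs WT changed with total reads, where the SPL-targeting list was lost (fry adjusted p = 0.148). The transposon-like list was called in its place (fry adjusted p = 0.0101, against 0.132 in the fit of the report).

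For the named miRNAs 864 values kept direction and side of the threshold, 92 lost a call, 21 gained one and 33 changed sign. With total reads only, which removes a shift of -0.62 in KD vs WT, the KD vs WT log2 fold changes became 0.018 for miR396a, 0.066 for miR166k, 0.105 for miR396c, 0.156 for miR1862a, 0.434 for miR166a, 0.405 for miR390 and 0.464 for miR444b. OE vs KD became -0.19 for miR167d, -0.385 for miR159a and -0.434 for miR820a. The shift of the scaling accounts for these. For miR168a, OE vs WT became 0.289 with DESeq2's size factors and with DESeq2, 0.123 with at least 10 CPM and 0.106 with isomiRs. For miR528, OE vs KD became 0.227 with DESeq2's size factors, 0.229 with DESeq2, 0.185 with 2 groups only, 0.028 with no filter, 0.127 with at least 10 CPM and 0.007 with isomiRs. With isomiRs miR820a became -0.074 in OE vs WT and -0.117 in KD vs WT; the cause was not tested. None of miR168a in OE vs WT, miR528 in OE vs KD or miR820a passed in the edgeR test of the report.

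Leaving out each library in turn gave 27 to 32, 20 to 27 and 17 to 23 miRNAs, and 10996 to 11302, 4846 to 6273 and 11284 to 11721 sequences, the 4846 without KD replicate 1. OE minus WT ranged from -10.3 to -6.60 percentage points for 21 nt, 1.07 to 1.79 for 22 nt and 1.29 to 5.53 for 24 nt. KD minus WT ranged from -1.14 to 2.61, 0.333 to 0.664 and -3.97 to 0.267. Signs changed for miR168a in OE vs WT (-0.019 to 0.018), miR156a (-0.117 to 0.559), miR159a (-0.034 to 0.566) and miR820a (-0.015 to 0.372) in KD vs WT, and miR159a (-0.032 to 0.567), miR172a (-0.94 to 0.715) and miR528 (-0.303 to 0.202) in OE vs KD.

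With at least 10 CPM, 21 miRNAs differed between OE and WT, as fewer were tested. The sequence counts were 29519, 16531 and 30670 with at least 2 CPM and 2620, 1591 and 2624 with at least 20 CPM, where 50134 and 3007 sequences were tested. DESeq2 called 4778 sequences in KD vs WT; the cause was not tested. Without adapter and cassette sequences the counts were 12017, 7141 and 12358. Counting distinct sequences in place of reads, OE minus WT was -0.520 percentage points for 21 nt and -0.979 for 24 nt, against -8.47 and 3.41 for reads, so the 24-nt difference changed sign. Distinct sequences were not counted at matched depth, and the cause was not tested. The windows and the OsRDR4 locus were not run, as no genome was used. The filter of the fit of the report left out sequences below 5 CPM and miRNAs below 1 CPM. They were tested only with lower minimums, down to 2 CPM for sequences and 1 read for miRNAs.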

Other observations

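The test of pairing in this part was chosen after the result was seen, and the sequences named here were chosen after their values were seen. The search took KD sequences outside the cassette, within 1 nt of 21 nt, with at least 20 reads in each KD library. They had at most 3 reads in WT and OE together. The most read was TGTGAAACAGTTAATAGCCGA, with 2706 reads in KD (126 ± 8.82 CPM, SD, n = 2), 2 in WT and 1 in OE. Its best partner among 55 KD sequences searched was TCTTCGGCAATTTACTGTTTC, with 1056 reads in KD (48.9 ± 0.279 CPM) and 0 in WT, at least 410-fold above the WT floor. They pair at 16 of 18 bases, and the best of 10000 random sequences paired at 14. The pair may be an artificial miRNA duplex of the knock-down construct, a hypothesis that the pairing of 16 bases does not settle, since the labels do not give the construct.

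The 21-nt sequence AGAAGAGAGAGAGTACAGCCT, which has 1 mismatch from the listed miR529b, stood at 5364 ± 1080 CPM in WT, 5521 ± 182 in OE and 11746 ± 2241 in KD. The 24-nt TTCGGCTTTGGACCAGCTTGGCCT stood at 1001 ± 1.49 CPM in KD, and the 21-nt CCTTCTGTACTGAACATGCCT at 4079 ± 592. Reads of 21 nt that end in CCT made up 17.9% ± 0.295 of the 21-nt reads of WT, 13.9% ± 0.480 of OE and 20.2% ± 1.11 of KD, and 6.71%, 6.23% and 6.36% of the distinct 21-nt sequences.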
